A study of Mus musculus with 12 samples.

How the data were processed

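Expression in mouse pancreas was measured on 12 Affymetrix arrays, 3 for each of 4 groups: C57BL6/NHsd and C57BL6/J mice, each after cerulein and after saline. Per the labels each array is a separate mouse of 8 weeks. RNA was extracted with Trizol and purified on RNeasy columns, and biotin-labelled cRNA was made from 100 ng of total RNA, per the labels' protocols. The deposited values are log2 probe set signals on the GCRMA scale, which the authors normalized across the 12 arrays; the submitters' processing notes name GCRMA and Partek without a version, and further steps are not stated. The table held 45101 probe sets, with a floor of 2.39 shared by all arrays and a highest value of 16.4. The values were used as deposited, with no further normalization in the main analysis.

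Probe sets were assigned to genes by the annotation of the array. Of the 45101 probe sets, 34958 carried 1 gene symbol; the 932 with several symbols and the 9211 without one were left out of the comparisons of genes. The Entrez numbers of 34754 probe sets were found in the RefSeq gene table, and 0 symbols needed updating. A probe set was kept where it exceeded log2 4 on at least 3 of the 12 arrays, which 14296 did, 12780 of them with 1 gene. A gene was represented by its kept probe set with the highest mean, which left 8505 of 18194 genes. Probe sets of related genes, such as the hepcidin, kallikrein and immunoglobulin genes, can bind each other's transcripts, so their values may belong to more than 1 gene.

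Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 12 arrays (8 residual degrees of freedom, median prior degrees of freedom 4.37), with moderated statistics and an intensity trend, two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 8505 genes. The 6 comparisons were cerulein against saline as the mean of both substrains and within each, the difference of that effect between substrains, and J against NHsd in saline and after cerulein. Where a gene lay under log2 4 on all arrays of 1 group, the change was given as at least the fold against log2 4, within each substrain for cerulein against saline. Where only some arrays of a group lay under log2 4, the measured change was kept, and its size is inexact where the group's mean was under log2 4. Lists of genes for cell types and pathways, fixed before the data were examined from textbook knowledge, held 655 entries, of which 596 matched a probe set. The 25 lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists, and again with a correlation estimated from the data. Lists of genes known to differ between the J and N lineages and of sex-specific genes were given as values. A list's shift is its mean log2 change minus that of all other tested genes.

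The named genes were chosen by a rule fixed before the data were examined: for each comparison, the 5 called genes with the largest rise and the 5 with the largest fall whose arrays do not overlap (no such condition for the difference of effects), up to 2 called members with the largest change from each of the 10 lists with the smallest camera p, and all measured members of the lineage and sex-specific lists. Genes chosen after their values were seen are named as such. Of the lineage list, 6 genes were tested; Crb1, Nlrp12, Zp2, Adcy5, Pdzk1 and Acnat2 did not pass the filter and Entpd4 had no probe set of its own.

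Comparisons of single values per array used exact permutation tests, two-sided, with 924 assignments for 6 against 6 arrays and 20 for 3 against 3, whose smallest p is 0.1. Correlations across genes served as descriptions. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

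The pipeline was tested on simulated data of 8505 genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Noise was normal and independent between genes, with no floor and no shift common to all genes. The shares recovered may differ where many more genes change, as after cerulein. For a comparison of 2 groups of 3 arrays (NHsd), the pipeline recovered 17.9% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 98.5% of those changed 4-fold. For the difference of effects the shares were 7.46, 22.4 and 95.5%, and for the mean of both substrains 47.8, 89.6 and 100.0%. The alternatives tried were quantile normalization, shifting each array to the same median, no filter on low values, a filter at log2 6, no intensity trend, robust moderation, the mean of a gene's probe sets, only the groups compared, the replicate number as a term, a fold threshold of 2, an estimated correlation in camera, and leaving out each array in turn. Spike-in probe sets were given as values and not used to rescale the arrays. Raw scanner files were not used here.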

Results

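RNA from the pancreas of 8-week-old mice was measured on 12 Affymetrix arrays of 45101 probe sets, with 1 array per mouse. The mice belonged to the substrains C57BL6/J, from Jackson, and C57BL6/NHsd, from Harlan, called J and NHsd here. Each substrain held 3 mice with chronic pancreatitis induced by cerulein and 3 saline-injected controls. Cerulein is an analogue of cholecystokinin, the hormone that makes acinar cells release digestive enzymes. The deposited values were log2 signals between 2.39, a floor shared by all arrays, and 16.4. The share of probe sets above log2 4 averaged 26.7% ± 0.31 on the 6 saline arrays and 30.3% ± 0.67 on the 6 cerulein arrays (SD). The mean correlation of an array with the others of its group ran from 0.983, for J cerulein replicate 1, to 0.994. Xist, transcribed from the inactive X chromosome, lay between log2 9.52 and 11.5 on all 12 arrays, and the 9 probe sets of 3 Y-linked genes reached at most 3.37. The labels give the controls as female and no sex for the treated mice. With 3 arrays per group, the number of arrays limits the precision, and the median standard error (SE) of a log2 difference between 2 groups was 0.20.

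Control probe sets differed between treatments. The 7 hybridization spike-in probe sets, for RNA added from outside the sample, averaged log2 8.91 ± 0.15 (SD, n = 6) on cerulein and 10.89 ± 0.41 (SD, n = 6) on saline arrays, a difference of -1.99 (exact permutation test, two-sided, p = 0.00216, the smallest possible; adjusted p = 0.0108 over 10 tests). The 12 poly-A spike-in probe sets averaged 7.49 ± 0.58 and 10.17 ± 0.42, a difference of -2.68 with the same p. The Gapdh probe sets gave a 3′ minus 5′ gap of 0.83 ± 0.13 log2 after cerulein and 1.22 ± 0.20 after saline (SD, n = 6 each; exact permutation test, two-sided, p = 0.00649, adjusted p = 0.0406 over 25 tests). The same gap of beta-actin was 1.67 ± 0.12 and 1.97 ± 0.26 (exact p = 0.0455, adjusted p = 0.208). No processing batch is named in the labels, so treatment and a difference in the handling of the arrays cannot be told apart. The spike-ins differed less between substrains, by 0.45 on saline arrays and by 0.10 on cerulein arrays for the hybridization kind (exact permutation p = 0.3 and 0.6, smallest possible 0.1).

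The first comparison, cerulein against saline as the mean of both substrains (6 arrays against 6), asked which transcripts of the pancreas changed with chronic pancreatitis. Periostin (Postn), a matrix protein of fibroblasts, was at least 22.9-fold higher in NHsd and at least 25.0-fold higher in J (adjusted p over both 4.83e-08). The macrophage membrane protein gene Ms4a7 was at least 11.3-fold higher in NHsd and 15.7-fold in J, and Birc5, which encodes the mitotic protein survivin, at least 7.66-fold and 11.3-fold. The chemokine gene Ccl8 rose by 4.80 log2 (SE 0.35). Lcn2, for the iron-sequestering lipocalin 2, rose by 4.18 in NHsd (SE 0.40) and was at least 16.3-fold higher in J. Hamp2, one of the hepcidin genes, changed by -4.89 (SE 0.23), from log2 12.04 to 7.69 in NHsd and from 12.21 to 6.77 in J. The neuropeptide gene Gal (galanin) changed by -3.97 (SE 0.20). Itih4, for a heavy chain of the inter-alpha-trypsin inhibitor family, changed by -3.76 in NHsd (SE 0.24) and was at least 7.09-fold lower in J. Hamp changed by -3.10 (SE 0.22) and the small membrane protein gene Smim38 by -3.09 (SE 0.34).

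Of 24 measured digestive enzyme and granule genes, 20 fell, 1 rose and 3 did not pass the test in this comparison. With the arrays shifted to equal medians 23 fell and none rose, and with quantile normalization 12 fell and 2 rose. Pla2g1b, the pancreatic phospholipase A2, changed by -2.15 (SE 0.12) and the amylase gene Amy1 by -1.99 (SE 0.11). The trypsinogen gene Prss3, chosen after its values were seen, rose by 0.78 (SE 0.19). The list's median was -0.38 (camera adjusted p = 2.43e-18; adjusted p = 0.431 with an estimated correlation). In saline, 19 of the 24 genes had means above log2 14, on arrays whose highest value was 16.4, and whether differences are compressed there was not tested. All 21 measured macrophage markers rose, by a median of 3.17 log2, with Tyrobp, a signalling adaptor, 3.97 higher (SE 0.30; adjusted p of the list 2.55e-08, and adjusted p = 0.431 with an estimated correlation). All 23 proliferation genes rose, by a median of 2.70, among them Mcm6, of the replicative helicase, by 4.46 (SE 0.17; adjusted p of the list 6.49e-08, and adjusted p = 0.431 with an estimated correlation). In quantile-normalized values 22 of the 23 proliferation genes rose, and with equal medians 21.

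Of 21 matrix proteins other than collagens, 19 rose, such as lumican (Lum) by 3.67 (SE 0.19), and 2, Mfap2 and Fmod, did not pass (adjusted p of the list 0.00111, and adjusted p = 0.812 with an estimated correlation). All 11 matrix proteases and inhibitors rose, 8 of them under either other scaling, with cathepsin S (Ctss) 3.70 (SE 0.21) and the gelatinase Mmp2 3.65 (SE 0.31) higher (adjusted p of the list 0.00337, and adjusted p = 0.59 with an estimated correlation). Of 17 interferon-stimulated genes 16 rose, among them Ifi27l2a by 2.35 (SE 0.30), and Irf1 did not pass (adjusted p of the list 0.0154, and adjusted p = 0.812 with an estimated correlation). The OAS family gene Oasl2 was at least 1.11-fold higher in NHsd and 2.29-fold in J. These 6 lists of the 25 tested were the ones called, and 0 were called with an estimated correlation. Adjusted over the list alone, each of the 6 had the same number of changed genes as over all genes. Of 14 collagens 13 rose (9 with equal medians), with Col3a1 3.14 (SE 0.24) and Col1a2 3.07 (SE 0.34) higher, but the list was not called (adjusted p = 0.0534). It was called with quantile normalization (adjusted p = 0.00221), with no filter on low values (0.000638) and without J cerulein replicates 1 or 2 or NHsd cerulein replicate 3 (0.000228, 0.0474 and 0.0487). Of 14 stellate cell and myofibroblast genes 12 rose (8 with equal medians), such as the pericyte gene Rgs5 by 2.73 (SE 0.26) and Fap, fibroblast activation protein, by 2.20 (SE 0.19; adjusted p of the list 0.0534). All 14 islet genes rose, but 5 with equal medians, with the transport protein gene Ttr 1.56 higher (SE 0.16) and the hormone gene Ppy 2.22 higher in J (SE 0.29; adjusted p of the list 0.0534). The stellate cell and islet lists were called with quantile normalization (adjusted p = 0.0197 and 0.0125), with no filter (0.0489 and 0.00134) and without some single arrays (lowest adjusted p = 0.0254 and 0.0338).

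Among lists that were not called in this comparison, 14 of 18 duct and metaplasia genes rose and 3, the mucin gene Muc1 and the trefoil genes Tff1 and Tff2, fell. Of 16 acinar identity factors 6 rose and 3 fell, and with equal medians none rose and 8 fell. That list's median was 0.22 and its mean 0.15 while its test pointed down (adjusted p = 0.0974). Rbpjl, a transcription factor of acinar cells, was 0.90 higher (SE 0.18) and Mecom 0.86 (SE 0.13), neither of which passed with equal medians (adjusted p = 0.101 and 0.0518). Of 9 regenerating family and acute pancreatitis genes 4 rose and 1 fell (3 and 4 with equal medians), with the test pointing down against a median of 0.31 (-0.27 with equal medians). Of 7 antigen presentation genes 5 rose, all encoding MHC class II proteins or their invariant chain, and 1 fell (4 and 2 with equal medians). Of 13 chemokines and cytokines 12 rose and 1 fell (8 and 1 with equal medians and with quantile normalization), with Cxcl1 lower at -1.94 (SE 0.24). Of 24 unfolded protein response genes 15 rose and 5 fell (8 rose and 9 fell with equal medians). Of 28 oxidative phosphorylation genes 14 rose and 1 fell (3 and 15 with equal medians). Of 21 oxidative stress genes 10 rose and 5 fell (8 and 11). Of 14 STAT3 and acute phase genes 9 rose and 2 fell (4 and 4 with equal medians). Of 17 TGF-beta pathway genes 11 rose and 1 fell (7 and 5), and of 14 cell death and senescence genes 9 rose and 1 fell (7 and 4). Of 11 endothelial genes 5 rose and 2 fell (1 and 5 with equal medians). Of 8 B and plasma cell genes 4 rose (1 rose and 1 fell), of 7 adipocyte genes 1 rose (1 and 1). Of 4 mesothelial genes 3 rose (1 and 0), and of 3 neutrophil genes 1 rose (0 and 0). Adjusted over the list alone, 14 collagens (13 over all genes), 13 stellate cell genes (12), 7 acinar identity factors (9) and 21 unfolded protein response genes (20) changed, and the counts of the other lists not called stayed the same. Of the T and NK cell and mast cell lists 1 gene each was measured, Zap70, which fell to signals under log2 4 on all 6 cerulein arrays, and Kit, 0.34 higher (SE 0.19) and not called.

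Over all 8505 genes tested, limma called 5904, of which 5049 were higher and 855 lower after cerulein, or 85.5% higher, and 2082 rose and 184 fell at least 2-fold. The median gene was 0.49 log2 higher after cerulein, and the counts of risen and fallen genes hold only relative to that shift. After each array was shifted to the same median of these genes 2262 were higher and 3072 lower, or 42.4% higher, and with quantile normalization of the same genes 2599 were higher and 2797 lower. The spike-in differences of -1.99 and -2.68 separated the same arrays as these changes, and the Gapdh gap was smaller after cerulein on average without separating every array.

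**Figure D1:**
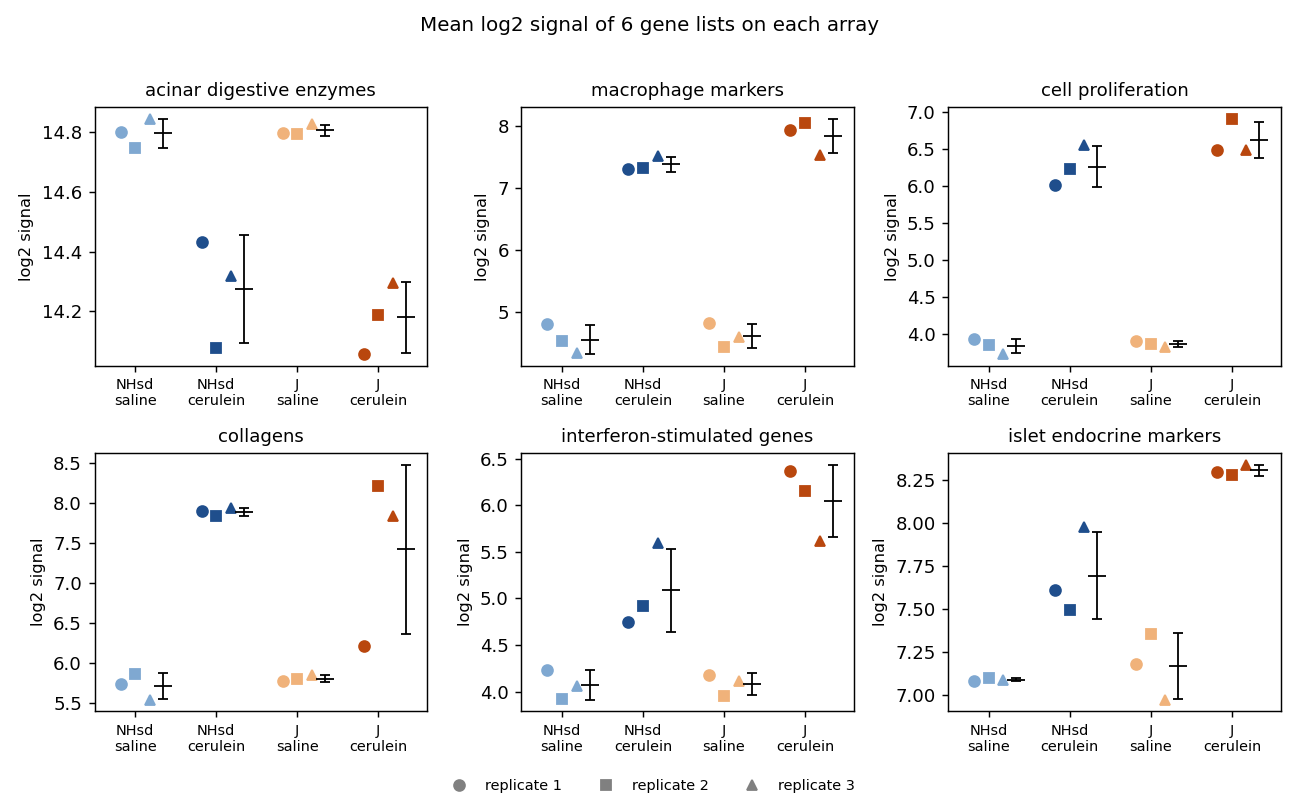
Mean log2 signal of the measured genes of 6 lists on each of the 12 arrays (points, with the shape giving the replicate) and the mean ± SD of each group of 3 (bars). The macrophage list lay at 7.30 to 8.06 on the 6 cerulein arrays and at 4.34 to 4.83 on the 6 saline arrays, and the collagen list of J cerulein replicate 1 lay at 6.22 against 7.84 to 8.21 on the other 5 cerulein arrays.

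In NHsd mice (3 arrays against 3), Postn was at least 22.9-fold, Ms4a7 at least 11.3-fold and the cartilage matrix gene Cilp at least 9.92-fold higher after cerulein, each from signals under log2 4 on all saline arrays. The tight junction gene Cldn2 was at least 7.48-fold higher, and Reg3g, a secreted lectin of the regenerating family, rose by 4.40 (SE 0.83). Hamp2 changed by -4.35 (SE 0.32), Itih4 by -3.76 (SE 0.24), Gal by -3.55 (SE 0.28), the kallikrein gene Klk1b24 by -3.08 (SE 0.44) and Hamp by -2.99 (SE 0.32). Of the digestive enzyme genes 17 of 24 fell (23 with equal medians, 7 with quantile normalization, by which 2 rose; adjusted p of the list 3.76e-17, and adjusted p = 0.391 with an estimated correlation). Pla2g1b changed by -1.92 (SE 0.18) and Ctrc, chymotrypsin C, by -1.86 (SE 0.21). All 21 macrophage genes rose, such as Mpeg1 by 4.03 (SE 0.29), and 22 of 23 proliferation genes (19 and 17 with equal medians), such as Mcm6 by 4.34 (SE 0.24; adjusted p = 4.55e-09 and 2.49e-08, and for both lists adjusted p = 0.391 with an estimated correlation). Of the other matrix proteins 19 of 21 rose and of the matrix proteases 11 of 11 (8 with equal medians), with Lum 3.80 (SE 0.26) and Ctss 3.58 (SE 0.29) higher (adjusted p = 0.000204 and 0.00132, and adjusted p = 0.847 and 0.476 with an estimated correlation). Mmp2 rose from log2 4.54 to 8.55 (SE of the difference 0.44). Collagens rose in 13 of 14 cases (9 with equal medians), with Col1a2 3.42 (SE 0.48) and Col3a1 3.34 (SE 0.33) higher (adjusted p = 0.0213, but 0.069 without NHsd cerulein replicate 2, and adjusted p = 0.847 with an estimated correlation). Adjusted over the list alone, 19 digestive enzyme genes (18 over all genes) and 20 other matrix proteins (19) changed, and the counts of the other 4 lists stayed the same. Outside the called lists, Cldn4 was at least 2.92-fold (4.67-fold without NHsd cerulein replicate 3) and Krt20 at least 2.84-fold higher, and 15 of 18 duct and metaplasia genes rose and 3 fell (12 and 3 with equal medians). Pdgfra, a receptor of fibroblasts, rose by 2.50 (SE 0.34). In all, 4139 genes were higher and 561 lower, with a median of 0.49 log2 over all genes, against 1721 and 2453 with equal medians. Cerulein minus saline, the spike-ins differed by -1.81 (hybridization) and -2.67 (poly-A) in log2 units, each with an exact permutation p of 0.1, the smallest possible.

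In J mice (3 arrays against 3), Ccl8 rose by 5.94 (SE 0.49) from a saline mean of log2 3.59, so that its size is not exact. Postn was at least 25.0-fold, Lcn2 at least 16.3-fold, Ms4a7 at least 15.7-fold and Birc5 at least 11.3-fold higher after cerulein. Hamp2 changed by -5.44 (SE 0.32), Gal by -4.39 (SE 0.28), Smim38 by -3.69 (SE 0.48) and the kallikrein gene Klk1b5 by -3.24 (SE 0.26). Itih4 was at least 7.09-fold lower. Interferon-stimulated genes rose in 16 of 17 cases, with Ifi27l2a 3.28 (SE 0.42) higher and Usp18, for a protease that removes ISG15, at least 3.02-fold higher (adjusted p of the list 0.000502, and adjusted p = 0.622 with an estimated correlation). Digestive enzyme genes fell in 18 of 24 cases (23 with equal medians, 13 with quantile normalization, by which 2 rose; adjusted p of the list 5.45e-17, and adjusted p = 0.265 with an estimated correlation). Pla2g1b changed by -2.38 (SE 0.18) and Amy1 by -2.18 (SE 0.15). All 21 macrophage genes and 22 of 23 proliferation genes rose (21 and 21 with equal medians), such as Tyrobp by 4.43 (SE 0.43) and Mcm6 by 4.59 (SE 0.24; adjusted p = 1.52e-10 and 4.46e-10, and for both lists adjusted p = 0.265 with an estimated correlation). Mmp7, for the protease matrilysin, was at least 14.3-fold higher, and 10 of 11 matrix proteases rose (7 with equal medians; adjusted p = 0.00243), as did 18 of 21 other matrix proteins (15 with equal medians; adjusted p = 0.000657). With an estimated correlation these lists had an adjusted p = 0.488 and 0.671. Of the islet genes 13 of 14 rose (6 with equal medians), with Ppy 2.22 (SE 0.29) and Ttr 1.85 (SE 0.22) higher (adjusted p = 0.00602), and of the stellate cell genes 12 of 14 (8 with equal medians; adjusted p = 0.0208). These lists had an adjusted p = 0.622 and 0.488 with an estimated correlation.

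The acinar identity list in J was called lower (adjusted p = 0.0239) although its median was 0.10 and its mean 0.06, with Rab3d, of secretory granules, at -0.84 (SE 0.15) and Rab27b at 0.92 (SE 0.28, not called with equal medians). This call ended without J cerulein replicate 1 (adjusted p = 0.0561), with no filter on low values (adjusted p = 0.462) and at adjusted p = 0.716 with an estimated correlation. Collagens rose in 9 of 14 cases and the list was not called (adjusted p = 0.174), but was with quantile normalization (adjusted p = 0.0115), with no filter (0.0109) and without J cerulein replicate 1 (5.03e-05), the array with the low collagen signals. Adjusted over the list alone, all 14 islet genes (13 over all genes), all 14 stellate cell genes (12) and 19 other matrix proteins (18) rose, and the counts of the other 6 lists called in J stayed the same. Of the chemokines 9 of 13 rose (6 with equal medians), such as Ccl6 by 3.06 (SE 0.27). In all, 4069 genes were higher and 647 lower in J, with a median of 0.47 log2 over all genes, against 1777 and 2497 with equal medians. The spike-ins of J differed by -2.16 (hybridization) and -2.69 (poly-A) in log2 units, cerulein minus saline, each with an exact permutation p of 0.1, the smallest possible.

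The cerulein effects of both substrains resembled each other. Across the 8505 genes, which are not independent replicates, they correlated with r = 0.888 (Spearman rho = 0.864) and a slope of 0.941 of J on NHsd. Limma called 3341 genes higher in both, against 1980 by chance, and 416 lower in both, against 42.7. The chance counts take the 2 effects as independent. Both effects hold a rise of the median gene (0.49 in NHsd and 0.47 in J) and the spike-in difference between treatments, which can raise the overlap. The overlap with equal medians was not tested. The growth factor gene Vegfa, singled out after its values were seen, was called in opposite directions, 0.79 higher in NHsd (SE 0.22) and lower in J at -0.55 (SE 0.22), with a difference of -1.34 that did not pass (adjusted p = 0.513).

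**Figure D2:**
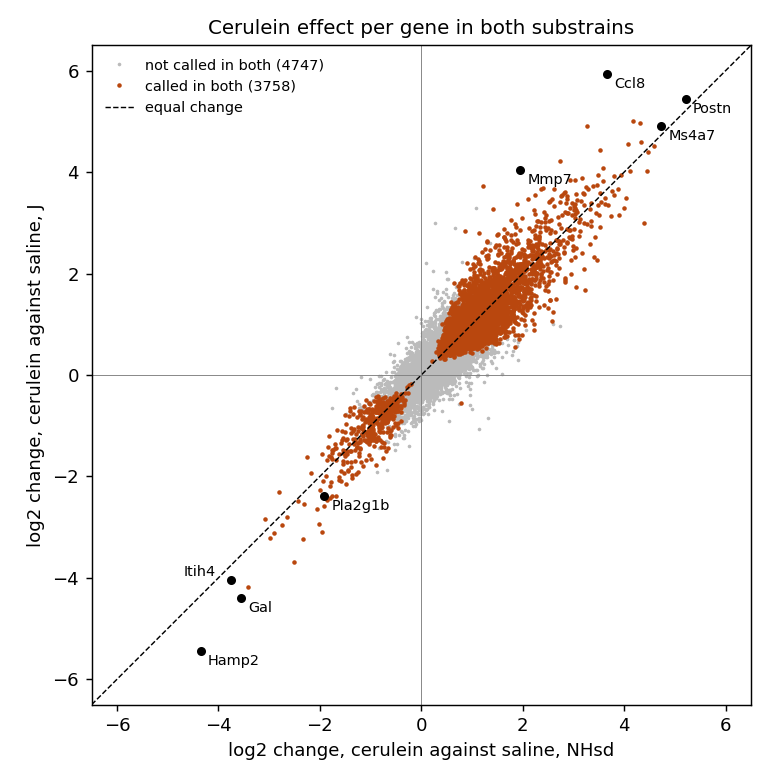
Log2 change of each of the 8505 genes after cerulein in J (vertical axis) against NHsd (horizontal axis), with the 3758 genes called in both in colour and a dashed line for equal change. Postn lies at 5.21 and 5.44, Hamp2 at -4.35 and -5.44, and Mmp7 at 1.95 in NHsd and 4.05 in J, with signals under log2 4 plotted as deposited.

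The difference of the cerulein effect, J minus NHsd (all 12 arrays), asked which responses to cerulein depended on the substrain. Mmp7 was the gene called, with an effect 2.10 log2 larger in J (SE 0.28, adjusted p = 0.0492). It was at least 3.43-fold higher after cerulein in NHsd and at least 14.3-fold higher in J, from saline signals under log2 4, so that 2.10 is not exact. As a group, the interferon-stimulated genes responded more in J, with a mean difference 0.96 above that of other genes and positive values for 16 of 17 (adjusted p = 1.26e-10; adjusted p = 0.353 with an estimated correlation). Ifit1, an antiviral effector, had the next smallest p after Mmp7 and did not pass (adjusted p = 0.0574). The islet list was 0.54 above other genes (adjusted p = 3.23e-06; adjusted p = 0.353 with an estimated correlation), and chemokines and cytokines 0.52 (adjusted p = 0.00419; adjusted p = 0.353 with an estimated correlation). With no filter on low values the chemokine difference was 0.23 and not called (adjusted p = 0.0623). Macrophage markers were 0.41 above other genes (adjusted p = 0.000662) and proliferation genes 0.35 (adjusted p = 0.00252), each with an adjusted p = 0.849 with an estimated correlation. The proliferation call ended without NHsd cerulein replicate 1 (difference 0.20, adjusted p = 0.11) or J cerulein replicate 2 (0.24, adjusted p = 0.149). Over all genes 0 members of these 5 lists passed limma's test. Adjusted over the list alone 6 interferon-stimulated genes, 3 chemokines, 1 macrophage gene and no islet or proliferation gene did.

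Collagens were called lower in the difference, at -0.55 against other genes (adjusted p = 0.0342), and oxidative phosphorylation higher by 0.15 (adjusted p = 0.0416), each with an adjusted p = 0.849 with an estimated correlation. Without J cerulein replicate 1 the collagen difference was 0.0447 above other genes (adjusted p = 0.902) and the oxidative phosphorylation difference 0.00135 (adjusted p = 0.902), while other matrix proteins (0.29, adjusted p = 0.0013) and the TGF-beta pathway (0.19, adjusted p = 0.0441) were called higher. The collagen call also ended without NHsd cerulein replicate 2, NHsd saline replicates 1 and 3 or J saline replicate 3 (adjusted p = 0.129, 0.0913, 0.0633 and 0.139). The oxidative phosphorylation call held only without NHsd cerulein replicate 1, J cerulein replicates 2 and 3 and J saline replicates 1 and 2, and ended with quantile normalization and with no filter (adjusted p = 0.061 and 0.0826). At an unadjusted p below 0.05 limma gave 598 genes. The call of Mmp7 ended with equal medians (adjusted p = 0.0554), with quantile normalization (adjusted p = 0.0856), with the filter at log2 6 (adjusted p = 0.0674) and without J cerulein replicates 1 or 2, NHsd cerulein replicate 1 or any of the 6 saline arrays (adjusted p between 0.0927 and 0.264).

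J against NHsd in saline (3 arrays against 3) asked how the substrains differ without pancreatitis. Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, of which J mice are known to carry a deletion, was lower in J, at -1.39 log2 (SE 0.14, adjusted p = 0.00244). The endosomal protein gene Wdfy1, also known to differ between the lineages, stood at -1.56 (SE 0.24, adjusted p = 0.0435), Itih4 at -1.66 (SE 0.24, adjusted p = 0.0365) and the immunoglobulin lambda gene Iglv1 at -4.19 (SE 0.57, adjusted p = 0.0331; J mean of log2 3.28, so that the size is not exact). Ugt2b34, a glucuronosyltransferase gene, was 1.91 higher in J (SE 0.28, adjusted p = 0.0365). Of the lineage list, Cyfip2, Ide, Trim12a and Kiz were measured and not called. Cyfip2 stood at -0.03, Ide at 0.36 and Kiz at 0.29, and Trim12a lay under log2 4 on all 6 saline arrays. The B and plasma cell list was lower in J (6 of 8 genes, mean -0.90 against other genes; adjusted p = 0.000711), as were the regenerating family (6 of 9 genes, mean -0.43; adjusted p = 0.00167) and 3 neutrophil genes (mean -1.89; adjusted p = 0.0123), each with an adjusted p = 0.495 with an estimated correlation. Over all genes 0 of their members passed, against 546 genes at an unadjusted p below 0.05 by limma, and adjusted over the list alone 2 B and plasma cell genes and 3 of the regenerating family did. The regenerating family's call ended without J saline replicate 2, where its mean was -0.11 against other genes (adjusted p = 0.13). The neutrophil call ended without that array or NHsd saline replicates 1 or 2 (adjusted p = 0.0993, 0.0976 and 0.0636). With no filter on low values 0 of these 3 lists were called (adjusted p = 0.178, 0.344 and 0.818), and Ugt2b34, Iglv1, Itih4 and Wdfy1 did not pass (adjusted p between 0.0544 and 0.0697). Fitted to only the groups compared, 0 of the 5 genes passed, with an adjusted p = 0.0628 for Nnt and Itih4. Nnt passed with each array left out in turn, while without 1 array the 5 calls ranged from 1, for each of NHsd saline replicates 2 and 3 and J saline replicates 2 and 3, to 9, for J cerulein replicate 1.

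J against NHsd after cerulein (3 arrays against 3) gave 14 genes higher and 5 lower in J. With equal medians 12 were higher and 10 lower, and with quantile normalization of the same genes 11 and 9, so the excess of higher genes depends on the scaling. The vitamin D-dependent calcium-binding protein gene S100g was 2.11 higher (SE 0.34, adjusted p = 0.0326), Usp18 2.10 (SE 0.31, adjusted p = 0.016), and Mmp7 2.06 (SE 0.20, adjusted p = 0.00116). The NHsd means of S100g and Usp18 were log2 3.42 and 3.50, under log2 4, so that their sizes are not exact. The annexin gene Anxa10 was 1.98 higher (SE 0.34, adjusted p = 0.0369), and Ifit1 at least 1.76-fold higher (adjusted p = 0.00116). Iglv1 stood at -3.63 (SE 0.57), Wdfy1 at -2.05 (SE 0.24) and Nnt at -1.35 (SE 0.14), all of which were also lower in J without cerulein. The other gene lower in both, Itih4, was at least 1.65-fold lower. Fetub, of the fetuin family, stood at -1.10 (SE 0.18). The interferon list was 0.90 above other genes (16 of 17 genes; adjusted p = 1.62e-12, and adjusted p = 0.238 with an estimated correlation), with a mean signal of log2 6.05 ± 0.39 in J and 5.09 ± 0.45 in NHsd (SD, n = 3). Of its genes, 12 passed adjusted over the list alone against 2 over all genes. The islet list was 0.55 above other genes (13 of 14 genes; adjusted p = 3.48e-09, and adjusted p = 0.228 with an estimated correlation), with Ppy 1.63 higher (SE 0.29) and 9 genes adjusted over the list alone against 1. The B and plasma cell list was lower (7 of 8 genes, mean -1.33; adjusted p = 2.87e-06, and adjusted p = 0.228 with an estimated correlation), with 5 genes adjusted over the list alone against 0. Macrophage markers were 0.40 above other genes (19 of 21 genes; adjusted p = 2.04e-05, and adjusted p = 0.436 with an estimated correlation), 3 adjusted over the list alone against 1, which was Folr2, a folate receptor of macrophages, at 0.99 (SE 0.16). With no filter on low values S100g, Usp18, Anxa10, Iglv1, Itih4, Fetub, Ppy and Folr2 did not pass (adjusted p between 0.0556 and 0.229).

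The other 6 lists called after cerulein rested on single arrays, and their lowest value was an adjusted p = 0.436 with an estimated correlation, for the chemokines. Collagens were lower in J (13 of 14 genes, mean -0.53; adjusted p = 0.000474) but 0.0656 above other genes without J cerulein replicate 1 (adjusted p = 0.507), and oxidative phosphorylation was higher by 0.09 (adjusted p = 0.0477) but -0.0569 without it (adjusted p = 0.579). The oxidative phosphorylation call also ended with quantile normalization (0.0493, adjusted p = 0.269) and without NHsd cerulein replicates 2 or 3 (adjusted p = 0.186 and 0.159). Without J cerulein replicate 1, lists not called with all arrays were called higher in J: other matrix proteins (0.44, adjusted p = 2.05e-09), matrix proteases (0.38, adjusted p = 0.000388), the TGF-beta pathway (0.21, adjusted p = 0.00524), stellate cell genes (0.24, adjusted p = 0.00532) and cell death genes (0.19, adjusted p = 0.0446). Digestive enzymes were lower (17 of 24 genes, mean -0.16; adjusted p = 0.00533), as were acinar identity factors (mean -0.16; adjusted p = 0.0224). Proliferation genes (mean 0.31; adjusted p = 0.000353) and chemokines (mean 0.27; adjusted p = 0.0477) were higher, the chemokines 0.13 and not called with no filter (adjusted p = 0.159). All 4 of these calls ended without NHsd cerulein replicate 1 (means -0.10, -0.09, 0.16 and 0.20, adjusted p = 0.169, 0.118, 0.0704 and 0.118). They also ended without J cerulein replicate 2 (means -0.12, -0.14, 0.20 and 0.27, adjusted p = 0.0665, 0.102, 0.102 and 0.102). The digestive enzyme call also ended without J cerulein replicate 1 (mean -0.10, adjusted p = 0.144). The identity and chemokine calls ended without NHsd cerulein replicate 3 as well (means -0.09 and 0.29, adjusted p = 0.18 and 0.0964). The chemokine and oxidative phosphorylation calls also ended without some saline arrays (adjusted p of at most 0.057). At an unadjusted p below 0.05 limma gave 800 genes. Mmp7, Ifit1, Wdfy1, Itih4 and Nnt passed with each array left out in turn, but 0 genes passed when only the groups compared were fitted (adjusted p = 0.107 for Mmp7, Ifit1, Wdfy1 and Nnt and 0.324 for Itih4). The 19 calls fell to 5 without NHsd cerulein replicate 1 and 7 without J cerulein replicate 1 and rose to 89 without NHsd cerulein replicate 3. Gapdh gaps differed between the substrains by 0.11 log2 after cerulein (exact permutation p = 0.4, smallest possible 0.1).

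**Figure D3:**
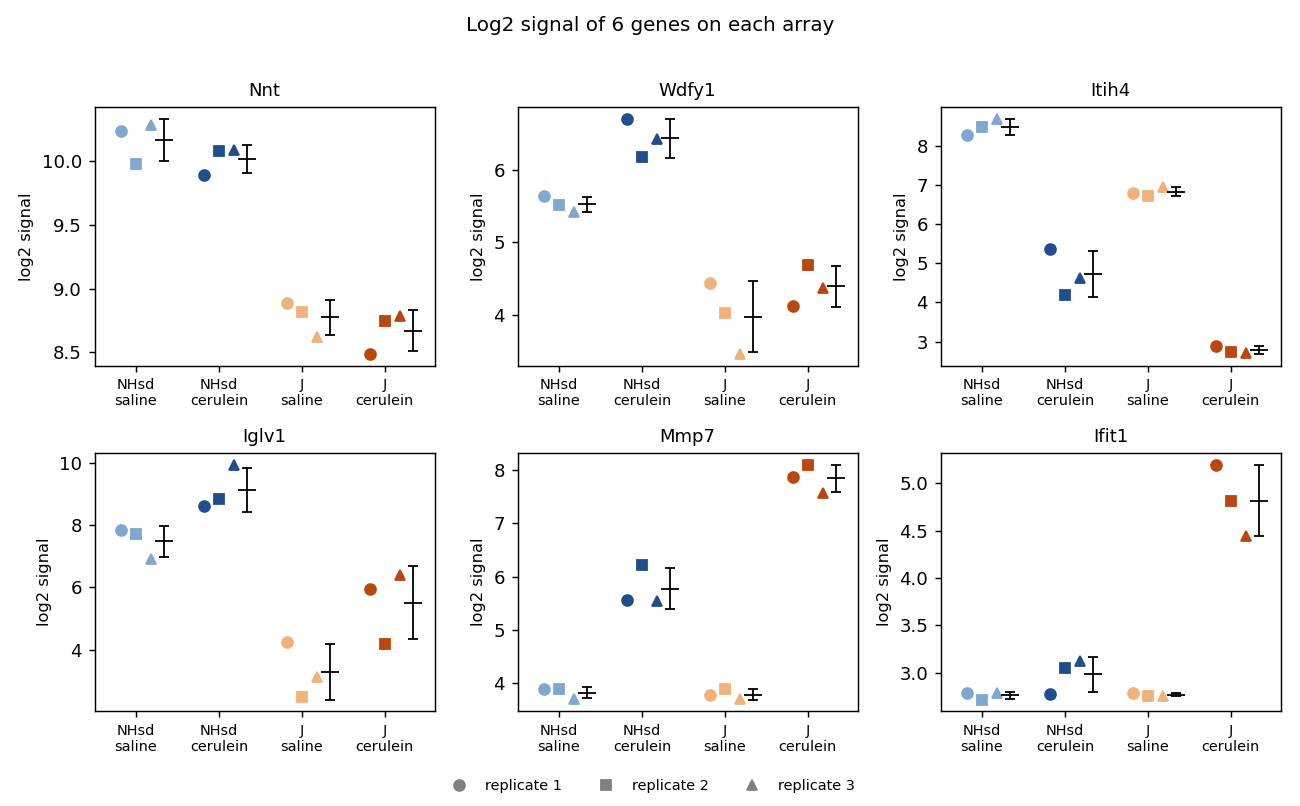
Log2 signal of 6 genes on each of the 12 arrays (points, with the shape giving the replicate) and the mean ± SD of each group of 3 (bars). Nnt lay between 8.49 and 8.89 on the 6 J arrays and between 9.89 and 10.28 on the 6 NHsd arrays, and Mmp7 lay at 3.70 to 3.89 on the saline arrays and at 7.57 to 8.08 on the J cerulein arrays.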

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

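The tests of marker lists against each other, of single arrays, of 3′ bias, of stellate cells and of collagens against genes of like span were chosen only after the results were seen, and the tests of RNA quality, scaling, gene span and other splits were chosen before. For scaling, the rule chosen before took the spike-ins as added in equal amounts, and a condition for unequal amounts, used below, was not part of it. A test of the difference of the cerulein response between the substrains passed for the gene Mmp7 (2.10 log2 larger in J, from saline signals under log2 4) and for 7 lists, whose mean differences against other genes follow. Interferon-stimulated genes stood at 0.96, islet genes at 0.54, chemokines and cytokines at 0.52, macrophage markers at 0.41, proliferation genes at 0.35, oxidative phosphorylation at 0.15 and collagens at -0.55. None of these 7 lists passed with an estimated correlation. Without J cerulein replicate 1 collagens stood at 0.0447 and oxidative phosphorylation at 0.00135, and with no filter on low values the chemokines stood at 0.23 (adjusted p = 0.0623). Mmp7 did not pass with equal medians (adjusted p = 0.0554), with quantile normalization (adjusted p = 0.0856) or without any 1 of 9 of the 12 arrays (adjusted p between 0.0927 and 0.264). Among the 1024 tested probe sets without a gene of their own, which the comparisons of genes did not use, 553 were higher and 109 lower after cerulein than in the saline controls.

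The number of genes called was set against other splits of the same arrays. For cerulein against saline over both substrains, 1 of 100 splits, the real one, gave 5904 genes and the highest other 2757. That share of 0.01 is the smallest that 100 splits can give, and makes a chance arrangement of the arrays unlikely. The splits cannot separate treatment from the handling of the arrays. For the difference of the effects, 6 of 100 splits gave at least the 1 gene of the real one, the highest other giving 12, so chance is not excluded for its count. For the 4 comparisons of 3 arrays against 3, 1 of 10 splits gave as many genes as the real one in each, and 10 splits are too few for a share under 0.05: the real counts and the highest others were 4700 and 0 in NHsd, 4716 and 0 in J, 5 and 0 in saline, and 19 and 1 after cerulein.

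More genes were called higher than lower after cerulein. RNA quality predicts a shift of the array medians of 0.0422 log2 from its slope within groups (95% interval -0.11 to 0.20), below the observed 0.58, which argues against it as the whole cause. A lower share of acinar cells with no other change would raise markers of all other cell types alike, but the macrophage minus endothelial difference rose by 2.72 (SE 0.17; exact permutation p = 0.00216, 6 arrays against 6). Both lists were picked after their values were seen, so the size of the difference is a description and its p is no independent evidence. Scaling of whole arrays cannot be told apart from a real shift. The hybridization spike-ins differed by -1.99 (SE 0.18), which by the rule chosen before would argue against scaling had equal amounts been added. That rule was not kept, since the poly-A spike-ins differed by -2.68, both differences lie far beyond the shift of the genes, and treatment is confounded with handling. The gain of macrophages, fibroblasts and dividing cells in pancreatitis remains open as a biological explanation and was not tested.

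Interferon-stimulated genes were higher in J than in NHsd after cerulein, in 16 of 17 genes. No single array decides this, since the list's adjusted p stayed at or below 1.08e-08 with each of the 12 arrays left out in turn, but the list was not called, at adjusted p = 0.238, with an estimated correlation. More macrophages in the J samples remain possible: the interferon list minus the macrophage list was 0.50 higher in J (SE 0.22, 3 arrays against 3), too small against its spread to decide, and the lowest J array (-1.92) lay close to the highest NHsd array (-1.93). The substrain itself, or a difference in housing between the suppliers' mice, may be the cause and was not tested.

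Collagens were low on J cerulein replicate 1, at a list mean of 6.22 against 7.84 to 8.21 on the other 5 cerulein arrays and 5.54 to 5.87 on the saline arrays, and less so other matrix proteins (6.35 against 6.99 to 7.81), mesothelial (4.90 against 5.53 to 6.01) and endothelial markers (4.75 against 5.11 to 5.44) and matrix proteases (6.55 against 6.81 to 7.52). The mean gap of 4 control transcripts showed no raised 3′ bias, at 1.12 on this array against 1.15 to 1.28 on the others, but it cannot decide on such a bias in other transcripts. Pyruvate carboxylase set this low mean (1.82 against 2.05 to 2.57), while Gapdh (0.83) and beta-actin (1.73) lay within the others' range. The transferrin receptor gap was 0.114 on every NHsd cerulein array and says little. The stellate list lay at 6.22, within the 6.05 to 6.64 of the others, but its mean does not decide on fewer stellate cells. Its members Pdgfra (6.64 against 7.41 to 8.07) and Rgs5 (7.78 against 8.29 to 9.17) were lowest on this array, while Fap (6.18) was not. Signal fell with gene span on this array (Spearman rho = -0.458 across genes, against -0.0688 to 0.11 on the NHsd cerulein arrays; J cerulein replicates 2 and 3, at 0.412 and 0.374, are set against a mean holding this array, which pushes them the opposite way), so a loss of signal from long genes is a candidate explanation for part of the pattern. Gene span alone was not the whole cause, since the 14 collagens lay a median of -1.70 (SD 0.78) beyond genes of like span. Span was measured along the genome, with introns. A loss that follows transcript length was not tested and remains possible. Low signals on this array were not limited to stromal genes. Among genes picked after their values were seen, Xist (9.76 against 11.15 to 11.50), Ide (7.42 against 8.10 to 8.80) and Rbpjl (6.56 against 7.18 to 8.04) were lowest there. Other genes, such as Tyrobp (9.52 against 7.90 to 8.59), were highest there. The poly-A spike-ins also stood apart on this array, at 8.67 against 7.13 to 7.36, and fewer stromal cells of other kinds were not tested as an explanation.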

How the results depend on the processing

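The alternatives were fixed before the data were examined. Across all settings, 2743 results of named genes kept their direction and side of the threshold, 167 lost and 16 gained a call, and 2 reversed; of lists, 2202 kept, 91 lost and 95 gained, and 6 reversed. The total counts of cerulein against saline, higher and lower genes together, stayed within 1.5 times under every setting except the filter at log2 6, which leaves fewer genes (3543 for the mean, 2955 in NHsd, 2890 in J), and the 2-fold threshold (2266, 2315 and 2349). The split into higher and lower genes did not hold. For the mean it went from 5049 and 855 to 2262 and 3072 with equal medians and to 2599 and 2797 with quantile normalization of the same genes. The call in the difference gave 0 genes with quantile normalization, equal medians and the filter at log2 6, 2 without the intensity trend and 15 with no filter on low values. With no filter, J against NHsd gave 37 genes in saline and 10 after cerulein, and 0 in both when only the groups compared were fitted, which leaves fewer arrays; for the other changes the cause was not tested.

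Lists called numbered 11 for the mean with quantile normalization, and with no filter 15 for the mean, 12 in NHsd and 0 in saline. With the correlation estimated in camera 0 were called in each of the 6 comparisons. With no filter the mean comparison reversed for oxidative phosphorylation (0.0714) and the unfolded protein response (0.30), and Kiz reached -0.51 both with quantile normalization and with equal medians. Replicate numbers gave no clear pairing of the mice (correlations of same-number arrays from -0.16 to 0.34, with 7 of 18 highest for their own number). Most of those 7 were of replicate 1, with r of at most 0.127, and an effect shared by the arrays of replicate 1 was not excluded. With the replicate block J against NHsd gave 2 genes in saline and 7 after cerulein, the other counts staying within 1.5 times.

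Leaving out each array in turn, where an arm of 2 arrays shares the spread of all groups, gave 5526 to 6151 genes for the mean, 3813 to 5257 in NHsd, 3931 to 4899 in J, 0 to 5 for the difference, 1 to 9 in saline and 5 to 89 after cerulein. The 89 came without NHsd cerulein replicate 3 and the 5 without NHsd cerulein replicate 1; without J cerulein replicate 1 there were 7. For the difference, 0 were called without NHsd cerulein replicate 1, J cerulein replicates 1 or 2 or any saline array, 2 without NHsd cerulein replicate 2 or J cerulein replicate 3, and 5 without NHsd cerulein replicate 3. Saline had 9 without J cerulein replicate 1, and 1 without replicates 2 or 3 of either saline group. Lists numbered 6 to 10, 5 to 7, 9 to 10, 5 to 10, 1 to 4 and 7 to 12 in the same order, the 1 in saline without J saline replicate 2. Without J cerulein replicate 1, 4 lists reversed: in the difference, collagens (range -0.91 to 0.0447) and other matrix proteins (-0.40 to 0.29), and after cerulein, collagens (-0.89 to 0.0656) and oxidative phosphorylation (-0.0569 to 0.19). Without that array other matrix proteins were also called higher in J, in the difference (adjusted p = 0.0013) and after cerulein (0.44, adjusted p = 2.05e-09), as were matrix proteases (0.38) and stellate cell genes (0.24) after cerulein. Signal over background limits the comparisons to the 8505 of 18194 genes above log2 4 on 3 arrays, folds are lower bounds where every array of a group is dimmer, and changes are inexact where only its mean is.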

Other observations

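The 3 lists here were chosen after seeing the data and given as member counts without a test of the list. Over all 8505 genes 5049 rose and 855 fell after cerulein (2262 and 3072 with equal medians). Anxa10, Cblif and Aqp5 lay under log2 4 on all saline arrays, so that they passed the filter only through the cerulein arrays. Genes of the stomach lining changed in the pancreas after cerulein: of 9 measured (17 listed), 6 rose and 3 fell over both substrains, with the same counts under quantile normalization and equal medians. Anxa10 was at least 5.05-fold higher in NHsd and 19.96-fold in J, and Cblif, the gastric intrinsic factor gene, at least 5.65-fold (8.52-fold without NHsd cerulein replicate 2) and 6.02-fold. Agr2 rose by 2.63 log2 (SE 0.23) and Ctse, cathepsin E, by 2.49 (SE 0.18), inexact sizes since saline means reached down to log2 3.85 and 3.88, while Tff2 fell by 1.41 (SE 0.10) and Tff1 was at least 1.53-fold lower in NHsd and 1.43-fold in J. Of these genes, 3 (Muc1, Tff1 and Tff2) also belong to the duct and metaplasia list. Of 6 measured tissue kallikreins (14 listed) 5 fell, 6 with equal medians, with Klk1b24 falling by 2.96 (SE 0.31) and Klk1b5 by 2.78 (SE 0.18), while Klk1 stood at -0.07 (SE 0.08) and did not pass. Klk1 lay between log2 15.45 and 15.91 on all 12 arrays, near the highest value of 16.4 on the arrays.

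Of 8 measured genes abundant in liver (18 listed), 5 rose after cerulein, 4 with equal medians, such as the fatty acid binding protein gene Fabp1, at least 3.50-fold higher in NHsd and 3.70-fold in J, and the albumin gene Alb, at least 2.76-fold and 2.42-fold. Without J cerulein replicate 1 the folds in J were at least 2.17 and 1.45. Over all 8505 genes 5049 rose, a like share, and 2262 with equal medians. Alb, Fabp1 and Mup3 lay under log2 4 on all saline arrays, so that they passed the filter only through the cerulein arrays. The list was highest on J cerulein replicate 1, at log2 6.56 against 5.39 to 6.05 on the other 5 cerulein arrays and 4.29 to 4.86 on the saline arrays, and Alb lay at 6.75 there against 4.45 to 6.24 on the other cerulein arrays.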
